A study of Ovis aries with 36 samples.

How the data were processed

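Total RNA from the infraspinatus of 9 female sheep was sequenced in 4 libraries per animal, 36 in all, with 3 animals in each of the arms CONTROL, N22W and N6W. The END and END-CC libraries of an animal come from the same occasion. The design text describes more animals per arm, of which 3 were analysed here. Per the labels' protocols, libraries were stranded total RNA libraries after depletion of ribosomal RNA with probes made for human RNA, and the submitters' processing notes name STAR 2.3.0e, R 3.0.2 and the sheep assembly Oar_v3.1 without saying what each served for. The tool and the annotation that gave the reads per gene, and the kind of size factor, are not given in the sources used here.

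The deposited files hold 1 signal per Ensembl gene identifier and library for 25197 genes, and their unit is not given in the sources used here. Each library's values are whole multiples of a single step of 0.51151 to 1.61525, written with at most 4 significant digits. They were therefore read as reads divided by 1 size factor per library. Values times that factor were checked: for values up to 100 reads, 100.0% lay within 0.1 of a whole number in the library with the lowest share. Reads recovered in this way summed to 11879736 to 43065773 per library. Libraries of a group were checked for copies of each other with a chi-square per gene of the reads of each pair, which ran from 7.24 to 32.12, where repeated draws from the same library would lie near 1.

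The size factors had a geometric mean of 0.999 over the 12 PRE and TR libraries of CONTROL and N22W (set A) and of 1.0 over the other 24 (set B), so the sets had been scaled apart. Set and group coincide in 6 of the 15 planned comparisons, which were not tested: repair in CONTROL and in N22W, nandrolone during repair in N6W against CONTROL, END against PRE and END-CC against PRE in CONTROL, and PRE of N6W against CONTROL. The comparison of N22W with CONTROL over 22 weeks subtracts changes that cross the sets alike and was kept.

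The test was chosen before the data were examined for the case of values other than whole counts: limma 3.58.1 with a mean-dependent prior on log2(value + 1), for the 16417 genes with a median of at least 0.5, in place of the edgeR test planned for whole counts. The authors' scaling was kept. Fold changes on this scale lie closer to 0 for genes with values near the pseudocount of 1. Changes within animals were fitted on all 36 libraries with the animal as a block and a mean for each arm and time point, and contrasts gave each change or difference of changes. Comparisons between animals at a single time point used the 9 libraries of that time point without a block. P values are two-sided and were adjusted by the Benjamini-Hochberg method over the 16417 genes of each comparison, with a false discovery rate of 0.05 as the threshold. CONTROL and N6W, untreated until repair, entered together for release. Of the 17 comparisons tested, 9 were planned, and 8 were added after the data had been examined: END against END-CC in N22W and in N6W, END and END-CC against PRE in N6W, END of either treated arm against CONTROL, and the difference between END and END-CC of either treated arm against CONTROL.

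The animal numbers pair the libraries, since the design text has the same animals give repeated biopsies. As a check, deviations from group means were correlated: libraries of the same animal had a mean r of 0.33 and libraries of different animals one of −0.16. Deviations within a group cancel out, so the negative value follows from the positive one and is no separate evidence. Each same-animal r exceeded 0.1 in 15 of 18 combinations of time points, and the lowest was −0.02.

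The release score of an animal is the mean log2 change of genes that rose minus that of genes that fell, with the genes called from PRE to TR in the other 8 animals. The score of the nandrolone genes is the mean log2 value of the genes with a higher change under nandrolone during release minus that of the genes with a lower change. Arms were compared with two-sided exact permutation tests of the mean, which reach at best p = 0.1 for 3 against 3 animals and 0.0119 for 3 against 6. Both scores, and the joint comparison of the treated arms with CONTROL, were added after the data had been examined, the score of the nandrolone genes after fold changes at END-CC had been seen. Whether nandrolone weakens the release change was asked, as planned, with genes called in a limma fit of the N6W PRE and TR libraries alone, whose spread comes from those libraries. The count for N6W animals alone elsewhere is a contrast in the fit on all libraries. Whether repair turns release changes back was asked with the release of CONTROL and the repair of N6W, since the other direction crosses the sets.

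None of the 25197 identifiers could be paired with a gene name: 0 matched, and 0 of the 35057 entries of the name table carry an Ensembl identifier. The planned tests of gene lists and scores per list were not run for that reason. Genes in the text were chosen by a planned rule, adapted because it asked for a name and for 5 genes in each direction: the 2 highest and 2 lowest log2 fold changes among genes that passed, with a mean of at least 1 CPM and the same direction in every animal (for a difference between arms, every animal of one above every animal of the other). The number of 2, and the limit to genes from untreated release and from nandrolone during release, which are then followed through other comparisons, were chosen after values had been seen.

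Alternatives, planned unless said otherwise, were edgeR 4.0.16 (quasi-likelihood test with RLE factors, and with TMM as an addition) and DESeq2 1.42.0 on the recovered reads, no filter on low values, no animal block, a fit of the libraries compared alone, and each animal left out in turn. Limma after TMM scaling, pseudocounts of 0.5 and 8, a median of at least 10, and the omission of the genes that part the sets were added after the data had been examined. Where an arm kept 2 animals the spread was pooled over all groups. Counts of genes were also obtained for other splits of the same libraries or animals.

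The limma fit was tested on simulated reads for the 16417 genes, 200 of them changed. The changed genes were drawn from those with a mean of at least 1 CPM, so the recovery does not cover genes with lower values. The simulation held no difference between animals or between the sets of libraries, and the same spread in every arm. It recovered, with the right sign, 90% of 2-fold and 100% of 4-fold changes for untreated release (16 unchanged genes called), 76 and 99% for release in N22W (6), 52 and 95% for nandrolone during release (9), 80 and 99% for repair in N6W (6) and 48 and 94% for nandrolone over 22 weeks (5). For END against END-CC in CONTROL it recovered 81 and 98% (11), for END-CC of N22W against CONTROL 47 and 94% (10), and for the difference between the sides of N22W against CONTROL 51 and 86% (8). Computations used R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.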

Results

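The infraspinatus, a muscle of the rotator cuff of the shoulder, was sampled in 9 female sheep whose infraspinatus tendon had been released and was reattached 16 weeks later. CONTROL animals received no drug. N22W animals received 150 mg of nandrolone decanoate, a slow-release ester of an anabolic steroid, every week for 22 weeks, and N6W animals received it every week for the 6 weeks that followed repair. Each of the 3 arms held 3 animals, and each animal gave 4 libraries of total RNA: the muscle before release (PRE), the same muscle at repair (TR), the same muscle 6 weeks later (END) and the muscle of the other side on that last occasion (END-CC). The 36 libraries form 12 groups of 3. Read totals per library, recovered from the deposited values, ran from 11879736 to 43065773, and 15433 to 18571 of the 25197 genes had a value above 0. The most abundant gene was the same in all 36 libraries and took 22.5 to 37.2% of the reads. Genes are given by their Ensembl identifiers, since no names could be paired with them, and values are reads divided by a size factor per library, as judged from their steps.

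The PRE and TR libraries of CONTROL and N22W, 12 in all, stood apart from the other 24. In every one of the 12 libraries 499 genes lay over 8-fold above their value in every one of the 24, and no gene lay so in the opposite direction. These 499 genes held 8.34 to 12.78% of the summed values in the 12 libraries and 0.0276 to 0.0538% in the 24. Changes within an arm were therefore tested only inside one of these sets, and the comparison of N22W with CONTROL over 22 weeks is between changes that cross them alike. Untreated release averages the change of CONTROL, inside one set, and that of N6W, inside the other, and nandrolone during release sets N22W against both. For 6 planned comparisons, among them the change over repair in CONTROL and N22W, set and group cannot be told apart, and they were not tested.

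Over the 16 weeks of tendon release without drug a large part of the transcripts of the muscle changed. In the 6 animals of CONTROL and N6W, which had received no nandrolone by then, 1707 genes rose and 2218 fell from PRE to TR, together 23.9% of the 16417 genes tested with limma at a false discovery rate of 0.05. Genes that rose had a median log2 fold change of 0.73 and genes that fell one of −0.43, and 553 of the former against 105 of the latter changed at least 2-fold. All 6 animals moved the same way in 2399 of the genes. The other side was not sampled at TR, so the change holds the 16 weeks that passed as well as the release.

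Among the genes that rose, ENSOARG00000003744 went from 3.46 ± 3.11 to 137 ± 116 normalized reads in CONTROL and from 4.86 ± 4.97 to 64.5 ± 45.3 in N6W (SD, n = 3 each), a log2 fold change of 4.09 (SE 0.61, adjusted p = 0.000118). ENSOARG00000012921 rose from 31.2 ± 20 to 272 ± 122 in CONTROL and from 14.4 ± 6.96 to 349 ± 86.8 in N6W (log2 fold change 3.88, SE 0.42, adjusted p = 8e-06). ENSOARG00000003501, an abundant transcript, fell from 45100 ± 23400 to 3720 ± 1420 in CONTROL and from 22000 ± 8170 to 5100 ± 3350 in N6W (log2 fold change −2.95, SE 0.37, adjusted p = 2.25e-05). ENSOARG00000019163 fell as well (log2 fold change −3.16, SE 0.93, adjusted p = 0.0158), from values that ranged from 18.08 to 7696 in the CONTROL PRE libraries. Its fall no longer passed the test without animal 2903 (−2.34), 2908 (−2.76) or 2909 (−3.14), nor without the animal term.

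The release changes of CONTROL and of N6W, which share no library and lie in different sets, had a Pearson correlation of 0.51 across genes, which are not independent replicates. By themselves CONTROL animals gave 691 genes that rose and 1152 that fell, and N6W animals 618 and 528. Of these, 193 rose in both arms and 281 fell in both, against 26 and 37.1 for independent lists, and 93.5% of the CONTROL genes had the same sign in N6W. Both lists use the spread per gene of the same fit, which can by itself raise their overlap above that of independent lists. The count for the 6 animals was 2533 when only their PRE and TR libraries were fitted, 2204 without animal 2902 and 2239 without animal 2909.

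**Figure D1:**
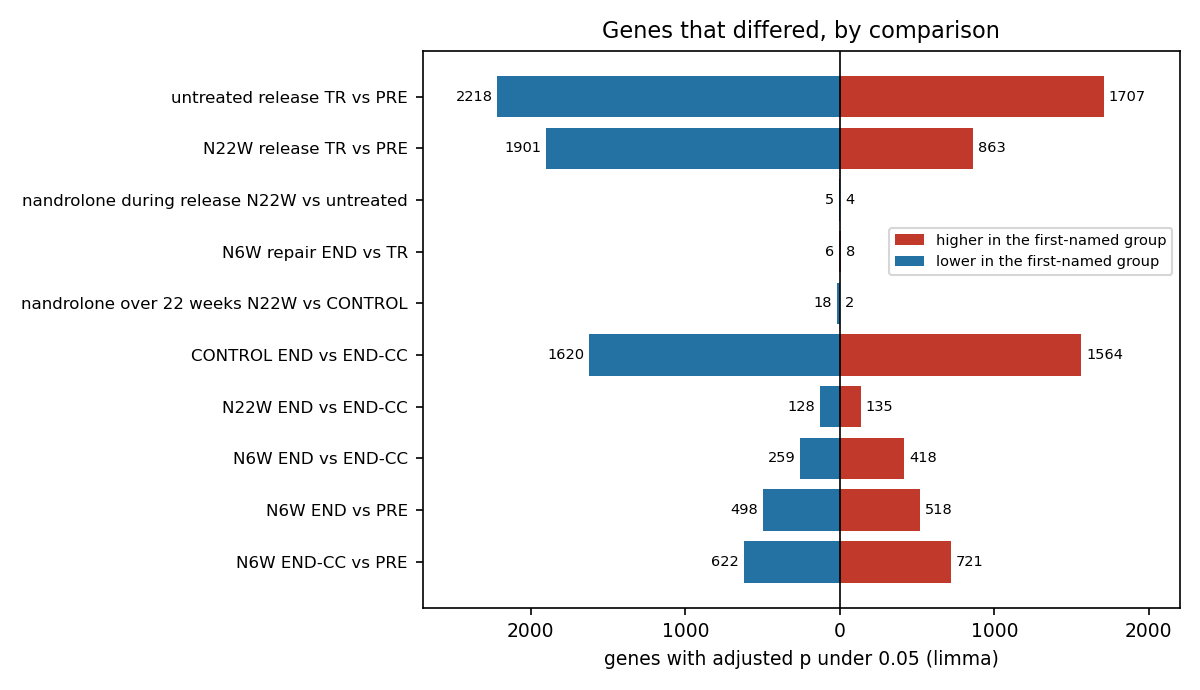
Number of genes higher (right) and lower (left) in the first-named group of each comparison with at least 1 gene past a false discovery rate of 0.05 in limma, among 16417 genes. From PRE to TR 1707 genes rose and 2218 fell in untreated animals, a change that holds the time that passed as well as the release. The operated muscle of CONTROL differed from the other side in 1564 and 1620 genes.

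From PRE to TR under nandrolone many genes changed too. The other side was not sampled at TR in this arm either, so release and the time that passed cannot be told apart. In the 3 N22W animals 863 genes rose and 1901 fell, with median log2 fold changes of 1.21 and −0.59. The balance between both directions moved with the method: 31.2% of the genes called rose, against 39.8% in limma after TMM scaling (915 rose, 1386 fell) and 48.7% in edgeR with TMM on the recovered reads (1231 and 1297). ENSOARG00000003744 rose from 5.65 ± 2.23 to 1500 ± 1100 (SD, n = 3; log2 fold change 7.56, SE 0.87, adjusted p = 8.04e-05), ENSOARG00000012921 rose with a log2 fold change of 5.03 (SE 0.60, adjusted p = 8.04e-05), and ENSOARG00000003501 fell from 17600 ± 3390 to 4240 ± 3580 (log2 fold change −2.36, SE 0.53, adjusted p = 0.00473). ENSOARG00000019163 rose in N22W (log2 fold change 4.45, SE 1.31, adjusted p = 0.0222), with TR values from 22.76 to 11870. That rise did not pass without animal 2914 (1.29, adjusted p = 0.512) or 2913 (5.45, adjusted p = 0.0787), without the animal term (adjusted p = 0.173) or with only the libraries compared (adjusted p = 0.139). The fall of ENSOARG00000003501 did not pass without 2913 (−1.99, adjusted p = 0.108), without 2915 (−2.15, adjusted p = 0.0749) or without the animal term (adjusted p = 0.0571). The N22W and the untreated changes share no library: 501 genes rose in both and 1227 fell in both, against 89.7 and 256.8 for independent lists. In opposite directions 11 moved, and 94.4% of the genes called without drug had the same sign in N22W. The shared spread per gene of the fit can by itself raise this overlap. The N22W count was 711 with only the libraries compared and 1438 without the animal term. It was 381 without animal 2913 and 458 without animal 2915.

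Few genes passed the test for a different response to release under nandrolone, a test that recovered 52% of simulated 2-fold changes. Against CONTROL alone limma called 0 genes, as given below. The change from PRE to TR differed between the 3 N22W and the 6 untreated animals in 9 genes, 4 with a higher and 5 with a lower change under the drug. ENSOARG00000003424 rose without drug, from 44.3 ± 7.72 to 130 ± 25.8 in CONTROL and from 30.9 ± 2.64 to 78.4 ± 26.7 in N6W, and fell with it, from 56.6 ± 25.2 to 20.9 ± 6.28 (SD, n = 3 each). The difference of its changes was −2.72 (log2, SE 0.46, adjusted p = 0.0195). ENSOARG00000007090 had a log2 fold change of 0.66 without drug (SE 0.19, adjusted p = 0.0141), 0.25 in CONTROL (adjusted p = 0.602) and 1.08 in N6W (adjusted p = 0.0184), and fell with it, from 385 ± 212 to 124 ± 24.9 (−1.49, SE 0.27, adjusted p = 0.00141), with a difference of −2.16 (SE 0.33, adjusted p = 0.0161). ENSOARG00000008705 rose under nandrolone from 123 ± 22.3 to 387 ± 15.4, against log2 fold changes of 1.66 with drug and −0.05 without (difference 1.71, SE 0.33, adjusted p = 0.0432). ENSOARG00000009832 rose from 17.8 ± 6.68 to 57.1 ± 9.70 under nandrolone, with log2 fold changes of 1.68 with drug and −0.08 without (difference 1.76, SE 0.33, adjusted p = 0.0425).

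The rise of ENSOARG00000007090 without drug did not pass without 2901 (0.59, adjusted p = 0.0578), 2903 (0.60, 0.0565), 2907 (0.51, 0.0779) or 2908 (0.59, 0.0676) or without the animal term (0.146), and its fall under nandrolone not without 2915 (−1.20, adjusted p = 0.0508). The fall of ENSOARG00000003424 under nandrolone did not pass without 2913 (−0.95, adjusted p = 0.207) or 2914 (−1.26, 0.0868).

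In this comparison edgeR also called 9 genes and DESeq2 36, and 1310 genes had an unadjusted p under 0.05 in limma. Against the 3 CONTROL animals alone, which lie in the same set as N22W, limma called 0 genes (1090 at an unadjusted p under 0.05), although the log2 differences of the 4 genes were −2.85, −1.75, 1.99 and 1.81 in the order given. Between the TR libraries directly they were −2.60, −1.83, 0.81 and 1.04: N22W lay below CONTROL at PRE for ENSOARG00000008705 (log2 difference −1.18, SE 0.33) and ENSOARG00000009832 (−0.77, SE 0.40), which enters their difference. Limma called 0 genes with only the libraries compared (1094 at an unadjusted p under 0.05) and 1 without the animal term. With a pseudocount of 0.5 it called 0 genes with a higher and 5 with a lower change. ENSOARG00000008705 and ENSOARG00000009832 therefore did not pass there. With animals left out the count was 0 without 2913 (776 at an unadjusted p under 0.05), 1 without 2902 or 2915, 2 without 2914, 3 without 2903, 6 without 2908 and 27 without 2909. Without 2913 none of the 4 genes passed, with log2 differences of −2.35, −1.96, 1.81 and 1.78 (adjusted p = 0.192, 0.15, 0.15 and 0.266). Of the other animals, leaving out 2902, 2903, 2907 or 2914 ended the call of ENSOARG00000003424, 2915 that of ENSOARG00000007090, 2902, 2903, 2907, 2908, 2914 or 2915 that of ENSOARG00000008705, and any of these or 2901 that of ENSOARG00000009832.

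A score of the 9 genes also differed between the arms in END-CC and END libraries, which had entered their choice through the estimate of the spread alone, although none of the 9 passed the test for single genes there: with both treated arms against CONTROL limma called 0 of them at END-CC and 0 at END (1163 and 1006 of all genes at an unadjusted p under 0.05, 0 by edgeR at either site). Their score, the mean log2 value of the 4 genes with a higher change minus that of the 5 genes with a lower change, was −3.02 ± 0.70 in the END-CC libraries of the 6 treated animals and −5.29 ± 0.34 in those of the 3 CONTROL animals (SD), so it was 2.27 higher under nandrolone in a muscle that had not been operated. In the operated muscle at END the score was −1.76 ± 0.95 in treated and −4.71 ± 0.70 in CONTROL animals, a difference of 2.95. Each of the 6 treated animals lay above each CONTROL animal at both sites. A two-sided exact permutation test of 6 against 3 animals gave p = 0.0119 for either site, the smallest value it can give, and 0.0417 after adjustment over 7 such tests. The score was formed after the fold changes of the genes at END-CC had been seen, so this p describes the libraries and is no independent test. For each arm alone the differences were 2.22 (N22W) and 2.32 (N6W) in END-CC and 3.67 and 2.23 in END, each with an exact permutation p of 0.1, the smallest possible for 3 against 3. At PRE, where N22W libraries had been used in the choice, the N22W score lay lower than that of CONTROL by a difference of −0.94 (exact permutation p = 0.1).

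**Figure D2:**
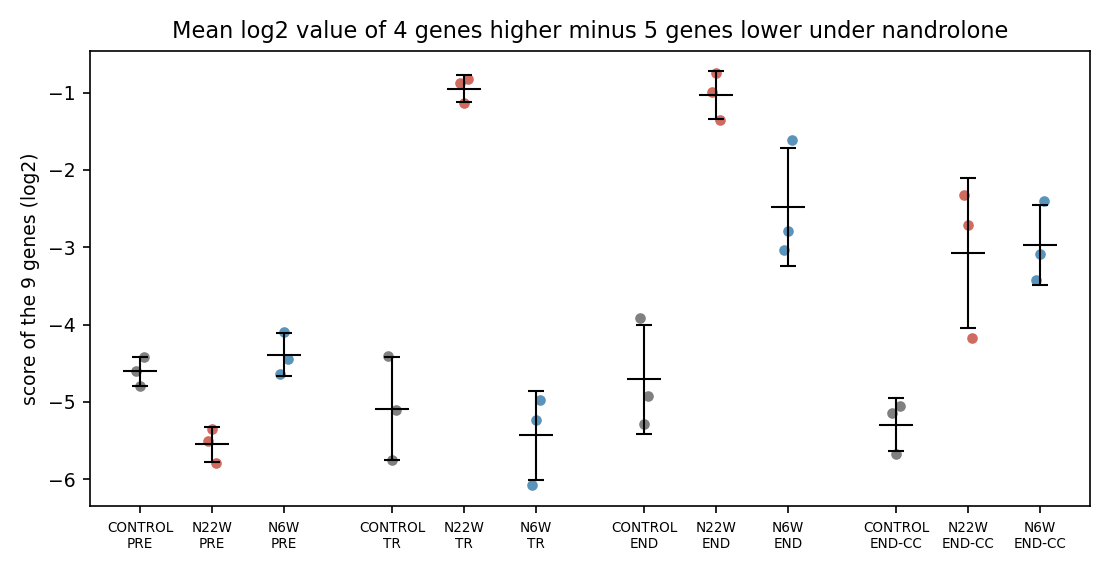
Score of the 9 genes whose change over release differed under nandrolone, per library (points) with mean and SD (black, n = 3), in log2 units, by arm and time point. In the END-CC libraries the 6 treated animals lie between −4.17 and −2.33 and the 3 CONTROL animals between −5.68 and −5.05; PRE and TR libraries served to find the genes.

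The 6 weeks after repair, spent under nandrolone in N6W, changed 14 genes in the operated muscle, of which 8 rose and 6 fell from TR to END. ENSOARG00000007090 was among those that fell, from 383 ± 160 to 140 ± 63.8 (SD, n = 3; log2 fold change −1.47, SE 0.27, adjusted p = 0.0296). The N6W TR libraries had also served on the untreated side when this gene was chosen. The choice therefore favours a fall over repair, and the fall is no independent test. ENSOARG00000003744 had a log2 fold change of 4.04 (SE 0.87, adjusted p = 0.0762), ENSOARG00000012921 one of 0.40 (SE 0.60, adjusted p = 0.887) and ENSOARG00000003501 one of 0.34 (SE 0.53, adjusted p = 0.895), none of them past the threshold. ENSOARG00000007090 did not pass without 2907 (−1.49, adjusted p = 0.0853) or 2908 (−1.37, adjusted p = 0.482). The count at an unadjusted p under 0.05 was 1628. edgeR called 24 genes and DESeq2 98, limma called 7 with only the libraries compared and 2 without the animal term. Limma called 0 genes without animal 2907 (1704 at an unadjusted p under 0.05) and 3 without animal 2908.

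Whether repair turned release changes back could be asked only with release changes from CONTROL and repair changes from N6W, which share no library. Repair in N6W was spent under nandrolone, so repair and drug cannot be told apart here. Of the 1843 genes called for release in CONTROL, 1280 (69.5%) had the opposite sign over repair in N6W. Genes with a median release change of 1.22 or −0.56 had median repair changes of only −0.07 and 0.12. The release score from TR to END in N6W was −0.09 ± 0.40 (SD, n = 3). It was 0.19 in animal 2907, −0.54 in 2908 and 0.10 in 2909. Over all genes, which are not independent replicates, the Pearson correlation was −0.07 and the Spearman correlation −0.16. For single N6W animals the Pearson correlation was 0.12 (2907), −0.23 (2908) and 0.02 (2909), and it was 0.09 without animal 2908. Among the 5817 genes with a mean above 10 CPM the Pearson correlation was −0.20 and the Spearman correlation −0.37.

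At the end of the experiment the operated muscle of N6W still differed from its state before release in 1016 genes, 518 higher and 498 lower. ENSOARG00000003744 had a log2 fold change of 7.51 (SE 0.87, adjusted p = 0.000128), ENSOARG00000012921 one of 5.01 (SE 0.60, adjusted p = 0.000128) and ENSOARG00000003501 one of −2.06 (SE 0.53, adjusted p = 0.021). ENSOARG00000003501 did not pass without 2907 (−2.17, adjusted p = 0.0556) or 2909 (−1.46, adjusted p = 0.169). The signs were those of the CONTROL release change for 86.1% of the genes called there. Limma called 0 genes with only the libraries compared (1719 at an unadjusted p under 0.05) and 372 without the animal term. The count was 486 without animal 2907 and 355 without animal 2909.

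Over the whole 22 weeks the change from PRE to END differed between N22W and CONTROL in 20 genes, 2 with a higher and 18 with a lower change under nandrolone. ENSOARG00000003424 differed by −3.09 (log2, SE 0.53), ENSOARG00000007090 by −2.22 (SE 0.38) and ENSOARG00000008705 by 2.25 (SE 0.38), each with an adjusted p of 0.0126. ENSOARG00000009832 differed by 1.48 (SE 0.38, adjusted p = 0.215) and did not pass. Part of the difference of ENSOARG00000008705 lay in the PRE libraries, with 123 ± 22.3 in N22W and 304 ± 172 in CONTROL (SD, n = 3; log2 difference −1.18), and END libraries compared directly gave 1.07 (adjusted p = 0.692), against −2.85 for ENSOARG00000003424 and −2.30 for ENSOARG00000007090 (adjusted p = 0.3 for both). These differences start from the PRE libraries that also enter the comparison over release, which by itself makes both alike. edgeR called 19 genes, DESeq2 52, and 1091 genes had an unadjusted p under 0.05. Limma called 0 genes without the animal term (674 at an unadjusted p under 0.05), in the END libraries alone (824) and in the difference between END and END-CC (753), where ENSOARG00000008705 had the opposite sign (−0.36). With 1 animal left out the count was 7 (without 2901), 5 (2902), 2 (2903), 8 (2913), 2 (2914) and 8 (2915). ENSOARG00000003424 then passed only without 2915, ENSOARG00000007090 only without 2913 or 2914, and ENSOARG00000008705 only without 2901, 2913 or 2915.

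The operated muscle differed from the muscle of the other side in each arm at END. In CONTROL 1564 genes were higher and 1620 lower on the operated side, with median log2 fold changes of 0.99 and −0.55. N22W had 135 higher and 128 lower genes, and N6W had 418 and 259, where DESeq2 gave a share of 48.0% higher against 61.7% in limma. ENSOARG00000012921 was higher on the operated side in CONTROL (409 ± 214 against 29.8 ± 14.5, log2 fold change 3.72, SE 0.60, adjusted p = 0.000582), in N22W (log2 fold change 3.57, SE 0.60, adjusted p = 0.00845) and in N6W (597 ± 476 against 68.8 ± 25.5, 2.78, SE 0.60, adjusted p = 0.0181; SD, n = 3 each). ENSOARG00000003501, which had fallen over release, did not differ past the threshold between the sides in CONTROL (−0.17, SE 0.53, adjusted p = 0.844), N22W (−0.68, SE 0.53, adjusted p = 0.499) or N6W (0.55, SE 0.53, adjusted p = 0.549), with means of 6360, 2600 and 4940 on the other side. ENSOARG00000003424 was higher on the operated side in CONTROL (log2 fold change 1.58, SE 0.38, adjusted p = 0.00684) and in N6W (1.31, SE 0.38, adjusted p = 0.0495) and had a log2 fold change of −0.02 in N22W (SE 0.38, adjusted p = 0.983), and the difference between N22W and CONTROL, −1.60 (SE 0.53), did not pass the test (adjusted p = 0.981). ENSOARG00000012921 did not pass without 2914 (3.57, adjusted p = 0.186) or 2915 (3.03, 0.0742) in N22W, nor without 2907 (2.86, 0.0561) or 2909 (1.78, 0.423) in N6W. ENSOARG00000003424 did not pass without 2901 (1.67, 0.0529) or 2902 (1.16, 0.11) in CONTROL, nor without 2907 (1.23, 0.137) or 2909 (1.04, 0.508) in N6W.

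Genes that differed between the sides largely shared their direction across arms. Between CONTROL and N22W 96 genes were higher in both and 108 lower in both, against 12.9 and 12.6 for independent lists, and 96.2% of the CONTROL genes had the same sign in N22W. For N6W the shared genes were 289 and 197, against 39.8 and 25.6, with 96.6% of the same sign. No library is shared by these comparisons, but all use the spread per gene of the same fit, which can by itself raise the shared counts. The difference between operated and other side was tested between arms itself, and limma called 0 genes for N22W against CONTROL (753 at an unadjusted p under 0.05, 0 by edgeR and 2 by DESeq2) and 0 for N6W against CONTROL (672, 0 and 0). The smaller counts in the treated arms are thus not a difference between arms that passed a test. Counts without the animal term were 1596 in CONTROL, 38 in N22W and 116 in N6W, and with only the libraries compared 3712, 791 and 0 (2409 at an unadjusted p under 0.05). They were 752, 1314 and 978 in CONTROL without 2901, 2902 and 2903, 41, 0 and 1 in N22W without 2913, 2914 and 2915 (1863 genes at an unadjusted p under 0.05 where the count was 0), and 318, 1213 and 2 in N6W without 2907, 2908 and 2909.

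A release score per animal gave the size of the change in genes called for release in the other 8 animals, as the mean change of genes that rose minus that of genes that fell. From PRE to TR it was 1.27 ± 0.25 in CONTROL, 1.30 ± 0.39 in N22W and 1.04 ± 0.87 in N6W (SD, n = 3 each), and N22W differed from the 6 untreated animals by 0.15 (two-sided exact permutation p = 0.714). Between END and END-CC it was 1.17 ± 0.18 in CONTROL, 0.81 ± 0.20 in N22W and 0.93 ± 0.84 in N6W. The 6 treated animals, with a mean of 0.87 ± 0.55, differed from CONTROL by −0.30 (two-sided exact permutation p = 0.417, adjusted over 6 such tests 0.857). Leaving out animal 2909 moved this value most: without it the difference was −0.49 (exact permutation p = 0.0357). That p is not adjusted over the 6 tests or over the animals left out in turn. N22W alone differed from CONTROL by −0.36 with an exact permutation p of 0.1, the smallest that 3 against 3 animals allow. In 33 genes called for release in a separate fit of the PRE and TR libraries of N6W, with their own spread, 29 that rose and 4 that fell, the same kind of score was 2.70 ± 0.35 in N22W and 2.93 ± 0.26 in CONTROL, a difference of −0.22 (exact permutation p = 0.5). It was −0.03 with the 500 genes of smallest p (exact permutation p = 1), −0.03 without animal 2914, −0.14 without 2901 and −0.37 without 2903 or 2915.

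**Figure D3:**
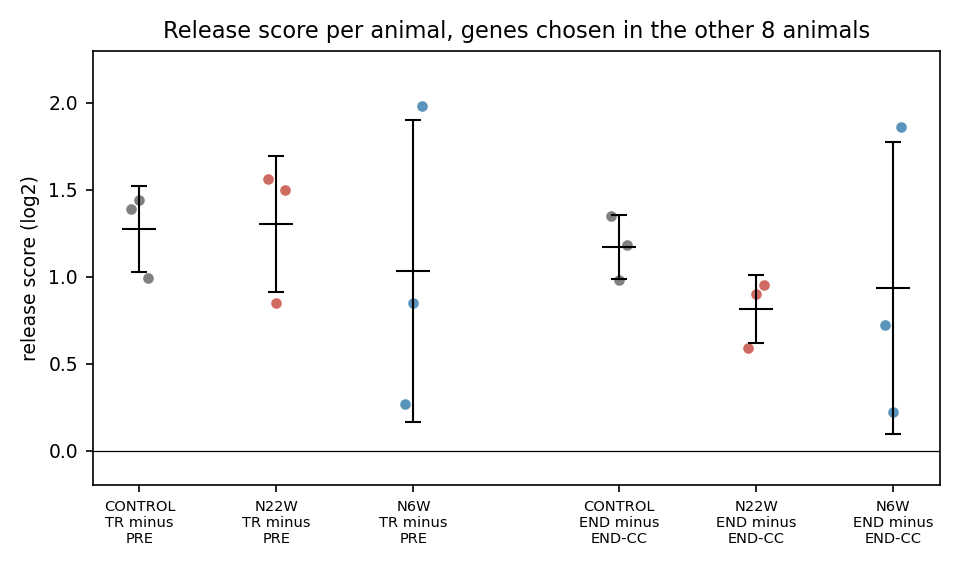
Release score in log2 units per animal (points) with mean and SD (black, n = 3), for the change from PRE to TR and the difference between END and END-CC, by arm. Scores run from 0.27 to 1.98 for release and from 0.22 to 1.86 between the sides, and the widest spread is that of N6W.

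Between the arms, the muscle of the other side at END-CC showed 0 genes in limma for N22W against CONTROL (1499 at an unadjusted p under 0.05, 0 by edgeR, 106 by DESeq2) and 0 for N6W against CONTROL (1140, 0 and 17). ENSOARG00000008705 reached 279 ± 154 in N22W, 293 ± 126 in N6W and 93.7 ± 5.42 in CONTROL (SD, n = 3 each), with log2 differences of 1.43 and 1.56 from CONTROL (SE 0.35 for both, adjusted p = 0.301 and 0.508). ENSOARG00000007090 had 117 ± 49.5, 108 ± 30.8 and 256 ± 106. In the operated muscle at END limma called 0 genes for N22W (824 at an unadjusted p under 0.05, 0 by edgeR, 54 by DESeq2) and 0 for N6W (1308, 0 and 49). Before release N22W and CONTROL differed in 0 genes as well (793, 0 and 21). With 1 animal left out these counts were 0 or 1, except for 3 genes for N6W at END without animal 2909.

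The muscle of the other side in N6W at END-CC differed from the N6W muscle before release in 1343 genes, 721 higher and 622 lower. ENSOARG00000003501 was lower (22000 ± 8170 at PRE, 4940 ± 5120 at END-CC; SD, n = 3; log2 fold change −2.61, SE 0.53, adjusted p = 0.0045), ENSOARG00000003744 was higher (4.31, SE 0.87, adjusted p = 0.00448) and so was ENSOARG00000008705 (1.12, SE 0.27, adjusted p = 0.0122). Of the genes called for release in CONTROL, 40.1% had the same sign in this comparison, and the release score was 0.02 ± 0.25. The count was 417 without the animal term and 0 in limma with only the libraries compared (3291 at an unadjusted p under 0.05). It was 272, 789 and 772 without 2907, 2908 and 2909. ENSOARG00000003501 did not pass without 2909 (−1.77, adjusted p = 0.0618), ENSOARG00000003744 not without 2907 (4.16, 0.0639) and ENSOARG00000008705 not without 2907 (1.13, 0.0789) or 2909 (0.80, 0.138).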

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

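The counts of genes and of splits were tested as planned, whereas the comparisons of N22W and N6W between the sides, of N6W with PRE and of the treated arms with CONTROL at END or in the difference between the sides, together with the release score, were added after the data had been examined.

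N22W differed from animals without drug in a few genes by some fits and not by others. The change over release differed in 9 genes between N22W and untreated animals, by a test of the difference itself. Of the 84 splits of the 9 animals 3 gave as many genes, the real one included, a share under 0.05. These splits mix the sets of libraries, and the share was not adjusted over the comparisons, so chance is not excluded. Inside one set, against CONTROL alone, limma called 0 genes (1090 at an unadjusted p under 0.05), and 0 with only the libraries compared (1094). The highest count in another split was 22, for animals 2901, 2907 and 2913, 1 of each arm, and the next was 12. Whether a structure of the samples beside the drug gave these counts was not tested. The change over 22 weeks differed between N22W and CONTROL in 20 genes, again by a test of the difference, and 1 of the 10 splits of 6 animals gave as many; 10 splits are too few for a share under 0.05 (real count 20, highest other 0). In the 8 sets of 6 animals searched for an animal far from the others, on the scores and on genes of untreated release, none was found.

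From PRE to TR without drug 3925 genes changed. Of 100 splits, drawn from 200 that keep 3 libraries of each arm on either side, 1 gave as many, the real one. Only 32 of these splits part the libraries of every animal, as the real one does. The others put both libraries of some animal on one side. The share was not adjusted over the comparisons, so chance is not excluded. The highest other split gave 3061 and is the real one with the libraries of animal 2907 exchanged, and the next gave 2924. For the comparisons that follow there are 10 splits, too few for a share under 0.05. Release in N22W called 2764 genes (highest other 1) and END against END-CC 3184 in CONTROL (highest other 1), 263 in N22W (0) and 677 in N6W (1), each reached by 1 of the 10. In N6W, END against PRE called 1016 (highest other 195, and 18 among splits that part every animal) and END-CC against PRE 1343 (highest other 6), also by 1 of the 10. Repair in N6W called 14 genes, which 2 of the 10 splits reached: the other gave 1283 with both libraries of animal 2907 and the END library of 2908 on one side. That count, far above the real one, points to a structure of the samples along animals; among splits that part every animal the highest other was 1.

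Where limma called 0 genes, 10 of the 10 splits gave as many, as they must for a count of 0, so the splits say nothing about chance there. The highest other counts were 2 for END-CC of N22W against CONTROL (1499 genes at an unadjusted p under 0.05, 0 by edgeR, 106 by DESeq2), 1 for END-CC of N6W (1140, 0 and 17), 2 for PRE of N22W (793, 0 and 21), 1 for END of N22W (824, 0 and 54) and 3 for END of N6W (1308, 0 and 49). They were 0 for the difference between the sides in N22W (753, 0 and 2) and in N6W (672, 0 and 0).

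Fewer genes differed between the sides in N22W (263) and N6W (677) than in CONTROL (3184). Animal 2913 had the lowest release score between the sides in N22W (0.59). It is argued against as the whole source: without it N22W had 41 genes, where CONTROL had at least 752 with an animal left out. N22W had 0 and 1 genes without 2914 and 2915, and its score difference from CONTROL went from −0.36 to −0.24 without 2913. A part played by 2913 therefore stays open. A smaller change of the same genes under nandrolone stays open, with a release score lower by a difference of −0.30 (exact permutation p = 0.417). Without animal 2909 the difference was −0.49, with an unadjusted exact permutation p of 0.0357. More spread between treated animals was not decided by its prediction: their mean score was 0.74 of that in CONTROL. The SD was 0.84 in N6W, whose count ran from 2 to 1213 with an animal left out, but 0.20 in N22W against 0.18 in CONTROL. The fit on all libraries pools the spread over the arms, so a gene has the same standard error in each arm (0.60 for ENSOARG00000012921). A wider spread in an arm therefore cannot lower its count through a larger standard error in this fit, where counts differ through the estimated changes.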

How the results depend on the processing

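Changes of scaling, pseudocount, filter, gene set and score genes, planned or added after the data had been examined, left each count within 1.5 times its value and each release score on its side of the threshold, except as follows, and the cause was not tested. DESeq2 gave 36 genes for nandrolone during release, 98 for repair in N6W, 52 over 22 weeks, 714 and 1235 for END against END-CC in N22W and N6W, 106 and 17 for END-CC of N22W and N6W against CONTROL, 21 for PRE, 54 and 49 for END of N22W and N6W against CONTROL, and 2 for the difference between the sides in N22W. edgeR gave 24 for repair with TMM and 24 with RLE. Nandrolone during release had 5 genes with a pseudocount of 0.5 (0 with a higher and 5 with a lower change) and 20 with one of 8 (8 and 12). A median of at least 10 left 1 gene with a higher and 5 with a lower change. Without a filter on low values the counts were 17 (nandrolone during release), 9 (repair), 117 and 413 (END against END-CC in N22W and N6W), 17 and 2 (END-CC of N22W and N6W against CONTROL), 18 (PRE) and 2 and 2 (END of N22W and N6W against CONTROL). Without the animal as a replicate block they were 1438 (release in N22W), 1 (nandrolone during release), 2 (repair), 0 (22 weeks; 674 at an unadjusted p under 0.05 in limma), 1596, 38 and 116 (END against END-CC in CONTROL, N22W and N6W), 372 (END against PRE in N6W) and 417 (END-CC against PRE); the block moved no other count by over 1.5 times. All 36 libraries without a replicate block gave 1 and 1 (END-CC of N22W and N6W) and 21 and 2 (END). Only the libraries compared gave 2533 (untreated release), 711 (release in N22W), 0 (nandrolone during release, 1094 at an unadjusted p under 0.05) and 7 (repair). They gave 791 and 0 for END against END-CC in N22W and N6W (2409 at an unadjusted p under 0.05 for the latter). For END and END-CC against PRE in N6W they gave 0 and 0 (1719 and 3291), and 1 for the difference between the sides in N22W. These fits have fewer libraries for the spread. That alone does not account for the lower counts, since END against END-CC rose to 791 in N22W and to 3712 in CONTROL. In N6W the counts of 677, 1016 and 1343 came from a fit with the spread pooled over all arms. Untreated release had 1843 genes in CONTROL alone and 1146 in N6W alone, from fewer animals. Nandrolone during release had 0 against CONTROL alone (1090 at an unadjusted p under 0.05) and 4 between TR libraries directly. Over 22 weeks limma called 0 between END libraries (824) and 0 for END minus END-CC (753), where ENSOARG00000008705 reversed (−0.36). With 1 animal left out, and so fewer samples, counts ran from 2204 to 4237 (untreated release), 381 to 2549 (release in N22W), 0 to 27 (nandrolone during release), 0 to 20 (repair), 2 to 8 (22 weeks), 752 to 1314, 0 to 41 and 2 to 1213 (END against END-CC in CONTROL, N22W and N6W), 355 to 961 and 272 to 789 (END and END-CC against PRE in N6W), 0 to 1 (PRE, and END-CC of either arm against CONTROL) and 0 to 3 (END of N6W). Release score differences from PRE to TR ran from −0.03 to 0.38 for N22W against untreated animals (negative without 2907). They ran from −0.11 to 0.26 for N22W against CONTROL (−0.11, −0.10 and −0.07 without 2903, 2913 and 2915). For N6W against CONTROL they ran from −0.71 to 0.14 (positive without 2907). Between END and END-CC they ran from −0.49 to −0.17 for treated animals against CONTROL, with an unadjusted exact permutation p under 0.05 only without 2909. For N22W alone they ran from −0.45 to −0.24 and for N6W from −0.70 to 0.12 (positive without 2908). The difference between N22W and CONTROL in genes called for release in N6W ran from −0.37 to −0.03, and the correlation of release with repair from −0.16 to 0.09. In the comparisons that called them in the main fit, genes given by identifier kept their direction and side of the threshold in 464 of 609 alternatives. They lost significance in 144 and reversed in 1. Comparisons in which these genes did not pass were not counted, so a gain of significance could not appear. Of the planned settings, those for the 6 comparisons across the sets and for gene lists were not run. Depth limits genes with low values: 16417 of 25197 genes reached the median of 0.5.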

Other observations

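The tests of the nandrolone score, of the 50 genes over release and repair, and of the sets of libraries were chosen after the results had been seen, the joint comparison of the treated arms was added after the data had been examined, and the tests on N6W at END-CC were chosen before their values were seen.

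A hypothesis was that the 9 genes whose change over release differed under nandrolone respond to the drug in muscle at large, operated or not. In END-CC, a muscle without surgery, their score was 2.27 higher in the 6 treated than in the 3 CONTROL animals (two-sided exact permutation p = 0.0119, the smallest possible). That test was chosen with the fold changes at END-CC in view, so it restates what prompted it and leaves the hypothesis open. Against CONTROL 9 of the 9 genes had the direction of the release comparison in N22W and 8 of the 9 in N6W, but both use the same CONTROL libraries, so these counts are not independent. At PRE, before any drug, the N22W score differed from that of CONTROL by −0.94, so the release difference starts in part from PRE.

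Calls for a wider response depended on the method. Against CONTROL, limma with the filter on the 9 libraries of a time point and edgeR called 0 genes for either arm at END-CC and at END (1499 for N22W and 1140 for N6W at an unadjusted p under 0.05 in limma at END-CC, 824 and 1308 at END). DESeq2 called 106 for N22W and 17 for N6W at END-CC and 54 and 49 at END, limma without the filter 17 and 2 at END-CC and 2 and 2 at END, and limma on all 36 libraries 1 and 1 at END-CC and 21 and 2 at END. Of the 50 genes with the smallest p for N22W against CONTROL over release, 40 (80%) had the same direction over repair in N6W, which shares no library, but 2 of the 10 splits of the 6 animals of N22W and CONTROL gave as many (highest other 41), and 10 are too few for a share under 0.05; across all genes the Pearson correlation was 0.17. With both treated arms together against CONTROL, limma called 0 genes at END-CC (1163 at an unadjusted p under 0.05, 0 by edgeR) and 0 at END (1006, 0 by edgeR), and DESeq2 was not run on the arms together. A count of 0 is reached by 84 of 84 splits whatever the data, so the splits say nothing about chance here (highest other counts 1 and 33). The 33 genes at END came from the highest of the other splits, and whether a structure of the END samples gave them was not tested.

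The PRE and TR libraries of CONTROL and N22W stood apart from all other libraries. Surgery, time and nandrolone are argued against, since before any of them 655 genes lay over 8-fold higher in every PRE library of CONTROL and N22W than in every PRE library of N6W. Depth is argued against too: in the 11 libraries of the larger set that are deeper than the shallowest of the smaller set, the 499 genes held at most 0.0511% of the values, against at least 8.34% in the smaller set. Size factors with a geometric mean of 0.999 in the smaller and 1.0 in the larger set are consistent with libraries handled in separate batches. What differed between such batches was not tested.

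In N6W the muscle of the other side at END-CC differed from the muscle before release in 1343 genes. Nandrolone is argued against as the whole source: in the direction of the change the median difference between N6W and CONTROL at END-CC was 0.12, below the limit of 0.186 set beforehand against a median change of 0.74, although 925 of the genes (68.9%) had the same sign. Low depth is argued against, since 1272 of the genes (94.7%) were also called among genes with a median of at least 10. A single animal stays open, as 272 genes were called without animal 2907. Age, season and the side of the body differ as well between PRE and END-CC and were not tested.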
